A study of Mus musculus with 4 samples.

How the data were processed

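RNA was measured in lung ILC2s of bleomycin-treated mice, in 2 WT (R5/+) and 2 KO (R5/+ Nrp1f/f) samples. Per the labels' protocols, each sample pooled 3 to 4 mice, RNA was extracted with Trizol at 7 to 14 ng/ul, full-length cDNA was made with the SMART-Seq HT kit and libraries with a TruePrep kit. Neither kit is described as marking strand. HISAT2, Cufflinks and the mm10 build are named in the submitters' processing notes, without roles. The counter, annotation release and filters are not given in the sources used here. Groups were taken from the genotype labels. A replicate is a pool, and nothing in the labels states a shared day, litter or batch.

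The data are the authors' own comparison of the genotypes. Per the file headers, the authors deposited a mean normalized count for each gene (baseMean, a signal averaged over the libraries), a log2 fold change with its standard error, also on the log2 scale, a test statistic (a score), a p-value and an adjusted p-value. The headings are those of a DESeq2 results table, per the file headers. The table also has 8 columns of values per library, headed by codes that match no sample label. They were assigned to no sample and enter no result, although their values were displayed when the file was first inspected. Depth per library, replicate agreement, per-sample levels, a refit, pairing and leave-one-out fits were therefore not analysed here.

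Checks of the deposited columns gave a statistic equal to the fold change over its error within 5.35e-08. Benjamini-Hochberg adjustment over the 19193 genes with a baseMean of at least 6.7 differed from the deposited adjusted p by at most 3.96e-05, and the other 19504 genes have none. The table does not state the numerator. Its name puts WT first, so the sign was turned and positive values here mean higher in KO. With the opposite reading all directions would turn, Nrp1 included.

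Before the data were examined, the plan was a linear model or count model on values per library and camera on the same values. With no column of values per library matched to a sample neither could be run, so the authors' test stands in for the first and cameraPR (limma 3.58.1 in R 4.3.3, inter-gene correlation 0.01) for the second, with Benjamini-Hochberg adjustment over the 33 lists. All lists were fixed before the data were examined and each had at least 5 members tested.

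The list statistic was changed after results had been seen, in 2 steps. Tested on simulated data with no change beside the abundance trend, the deposited statistic called 100 of 100 unchanged lists of genes with a baseMean of at least 1000 at a p under 0.05. Of such lists raised by 0.5 standard errors it called 0 of 20 as higher, and of those raised by 1 also 0 of 20. A running median over baseMean was first taken from the statistic itself, which called 9 lists higher and 2 lower on the real data. It was then replaced, because it inflates genes with wide errors, by the log2 fold change minus its running median, divided by the standard error. This form called 3 of 100 unchanged abundant lists, 1 of 100 unchanged lists of genes with wide errors, 15 of 20 lists raised by 0.5 standard errors and 20 of 20 raised by 1, over 19193 genes. The simulated errors were independent between genes, so these counts do not cover lists whose members vary together. Adjustment of 200 genes raised by 5 standard errors recovered 188. A list call thus says that members lie above or below genes of like abundance. An estimated correlation could not be computed, so it is not known which list calls hold with one. Tissue markers that vary together make the preset value too small.

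Named genes were 15 fixed in advance, the 10 largest rises and 10 largest falls past the threshold, up to 4 members of each list with the smallest p, and the most abundant member of each list of other cells. Predicted models were counted but not named, except a few singled out after their values were seen. Of the 161 named genes, 5 have no adjusted p. A gene among the largest falls is not reported here. The condition that libraries of the genotypes not overlap could not be applied. Gene positions and exonic lengths came from GENCODE M21, the same build as mm10, where 38427 of 38697 identifiers had a record.

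Genotype means per gene were derived from baseMean and the fold change, assuming equal weight of the genotypes. Tests on sets of genes in the closing section used bootstrap intervals or 10000 random sets, each member replaced by a gene within 100 ranks in baseMean. The bootstrap resampled genes, so its intervals do not measure the spread between pools. A set with a median baseMean under 6.7 was taken to decide nothing, a rule set after results had been seen. Tested on simulated data, the count of neighbouring pairs passed in 1 of 20 random sets and 20 of 20 sets with planted neighbours, and the length correlation in 20 of 20 simulations with reads in proportion to length and 0 of 20 without. The length simulations had no spread between pools and no loss of reads in near-identical copies. They do not show what rho genomic DNA would give here. Alternatives were no filter, a baseMean of at least 50, protein-coding genes with established names, an adjusted p under 0.1, and at least 2-fold with an unadjusted p under 0.05. Those chosen after seeing the data were centring on genes with a baseMean of at least 1000, the trend kept, the statistic minus its own trend, ranks, the fold change in place of the statistic, and random lists. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used.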

Results

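Gene expression was profiled in group 2 innate lymphoid cells (ILC2s), tissue-resident lymphocytes that make type 2 cytokines such as IL-5 and IL-13, sorted from the lungs of C57BL/6 mice given bleomycin, a drug used to injure the lung and induce fibrosis. Mice carrying R5, a reporter allele at the Il5 locus that also drives Cre recombinase, served as wild type (WT), and R5 mice with a floxed Nrp1 gene served as knockout (KO). Nrp1 encodes neuropilin-1, a co-receptor for semaphorins, VEGF and TGF-beta. There were 4 samples, 2 per genotype, each a pool of 3 to 4 mice. The values are the authors' comparison of the genotypes over 38697 genes, in which baseMean is a gene's mean normalized count over the libraries. Depth per library was not used here, and the baseMean values sum to 12974883. The comparison asks which transcripts differ in lung ILC2s when Nrp1 is deleted.

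Nrp1 (ENSMUSG00000025810, chromosome 8, 128358604 to 128503363, mm10) was lower in KO by a log2 fold change of -1.18 ± 0.21 (SE) at a baseMean of 3771, with an adjusted p of 1.27e-04 in the authors' deposited table. This is a gene-level value and does not isolate the floxed exon. Of the 19193 genes with an adjusted p, 87 were higher and 19 lower in KO at an adjusted p under 0.05 in the authors' deposited table. The rises were mostly in genes of few reads, 78 of 87 having a baseMean under 100, while 14 of the 19 falls were in genes with a baseMean of at least 1000. At an unadjusted p under 0.05 the counts were 1846 higher and 759 lower.

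**Figure D1:**
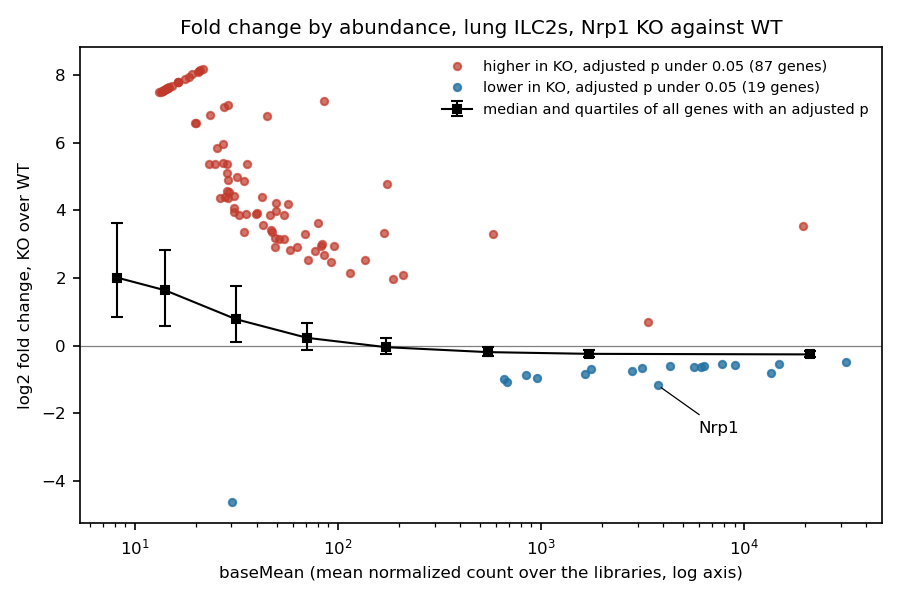
Log2 fold change (KO over WT, vertical axis) against baseMean (horizontal, log axis) for the 87 genes higher and 19 genes lower in KO at an adjusted p under 0.05; black squares and bars are the median and quartiles of all genes with an adjusted p, in bins of baseMean. The medians run from 2.01 in the lowest bin to -0.26 in the highest.

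After Nrp1, the authors' deposited table listed Eprs, the glutamyl-prolyl tRNA synthetase, at -0.81 ± 0.16 (adjusted p = 0.00152) and its neighbour Bpnt1, a bisphosphate nucleotidase, at -0.85 ± 0.21 (adjusted p = 0.0299). Cd3g, a chain of the T cell receptor complex, fell by 0.96 ± 0.24 on the log2 scale in the authors' deposited table, with an adjusted p of 0.0292. Nnt, the mitochondrial transhydrogenase, fell by 0.89 ± 0.23, the co-chaperone Stip1 by 0.76 ± 0.19 and the lipid transporter Abca7 by 0.71 ± 0.19 in the authors' deposited table. Rln3, which encodes relaxin-3, stood at -1.07 ± 0.28 in the authors' deposited table, and Rln3 and Il27ra lie 339 bp apart on the same strand, so reads from transcripts extending across the gap cannot be assigned with certainty here. Ighv1-53, an immunoglobulin heavy-chain variable segment, had the largest fall at -4.63 ± 1.17, at a baseMean of 30.1 in the authors' deposited table. When fold changes were centred on abundant genes, an alternative chosen after seeing the data, 225 genes were higher and 2 lower. Of the 19 falls, those of Nrp1 (adjusted p = 0.00994) and Ighv1-53 (0.0293) still passed.

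**Figure D2:**
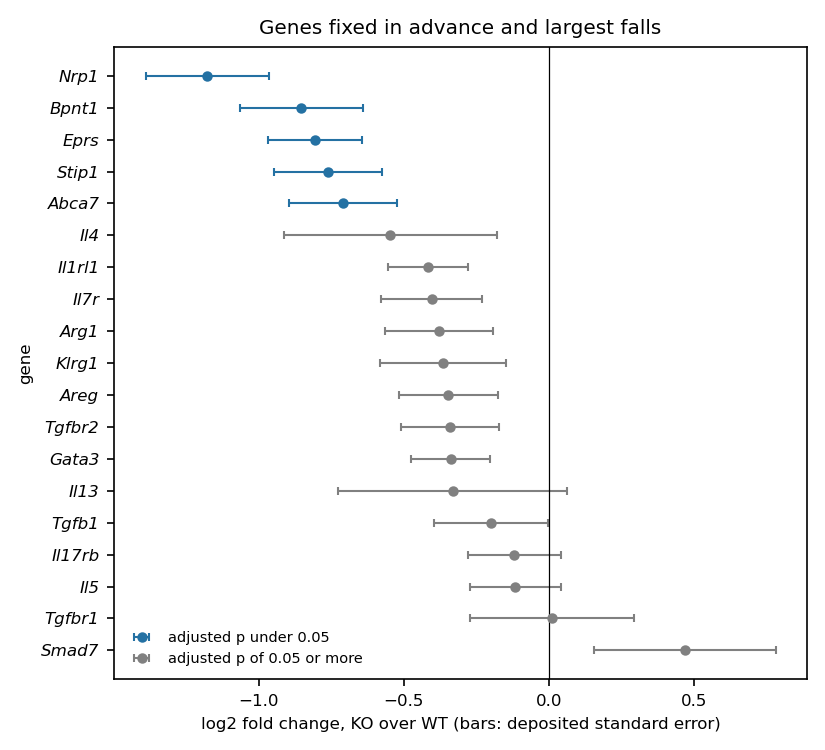
Log2 fold change (KO over WT, horizontal axis) with the deposited standard error for the genes fixed in advance and for the largest falls with a baseMean of at least 1000; blue marks an adjusted p under 0.05. Nrp1 lies lowest, at -1.18.

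Among the rises, Klf10, a TGF-beta-inducible transcription factor, was the only named gene with a baseMean of at least 1000, at 0.68 ± 0.18 (adjusted p = 0.0401) in the authors' deposited table. The other such gene was the predicted model Gm10800, named after its value was seen, at 3.53 ± 0.97 in the authors' deposited table. The immunoglobulin constant gene Ighg2b rose by 4.79 ± 0.55 (adjusted p = 3.37e-14) in the authors' deposited table, and Igkv4-91, a light-chain variable segment, by 7.25 ± 1.11. Of 52 immunoglobulin variable segments with an adjusted p, 5 passed the test as higher and 1 as lower, and 35 (67.3%) had a positive log2 value. Their median baseMean was 25.2, and of all tested genes with a baseMean of 20 to 50, 79.3% were positive. Of 9 constant genes, 1 passed as higher and 0 as lower, and 7 had a positive log2 value. The more abundant constant genes did not pass in the authors' deposited table, with Ighm at -0.51 ± 0.18 (adjusted p = 0.141), Igkc at 0.59 ± 0.64 (0.736) and Igha at 0.23 ± 0.63 (0.913). Immunoglobulin genes are markers of B and plasma cells, so these calls cannot be placed in ILC2s here. Beside Igkv4-91, at a baseMean of 85.7, the largest log2 values by the naming rule were those of Fsd1 (8.20 ± 1.84), Ephb1 (8.16 ± 1.96), Gabra2 (8.14 ± 1.88), Adcyap1r1 (7.81 ± 1.93), Ly6g6c (7.62 ± 2.06), Rpl3l (7.56 ± 2.06), Shox2 (7.55 ± 2.01), Ighv1-54 (7.50 ± 2.03) and S100a3 (7.13 ± 1.73) in the authors' deposited table, these with a baseMean under 30. For 31 of the 87 rises the deposited values imply a WT mean under 1 normalized count, so these log2 values are fitted quantities and give no measured fold.

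The type 2 programme of these cells showed few genes past the test. The deposited log2 fold changes of Il5, Il13 and Il4 were -0.11 ± 0.16, -0.33 ± 0.40 and -0.55 ± 0.37, with adjusted p of 0.798, 0.764 and 0.533 in the authors' deposited table, and Il5 became positive when centred on abundant genes. Areg, an epidermal growth factor family ligand, stood at -0.35 ± 0.17 (adjusted p = 0.341) and Arg1, arginase 1, at -0.38 ± 0.19 (0.340) in the authors' deposited table. Csf2, which encodes GM-CSF, fell by 0.62 ± 0.16 (adjusted p = 0.0335) and was the 1 of 20 cytokine and effector genes past the test in the authors' deposited table. None of 23 identity and surface genes passed, among them Gata3 (-0.34 ± 0.14, adjusted p = 0.211), Il7r (-0.40 ± 0.17, 0.256) and Klrg1 (-0.36 ± 0.22, 0.458) in the authors' deposited table. The cytokine list (adjusted p = 0.917 by cameraPR) and the identity list (0.917) did not pass. Among 28 alarmin and cytokine receptor genes, Il10ra fell by 0.56 ± 0.15 (adjusted p = 0.0423) in the authors' deposited table, and 8 were lower when adjusted over the list alone, including the IL-33 receptor Il1rl1 (-0.42 ± 0.14, 0.118 over all genes) and Il4ra (-0.46 ± 0.16, 0.124). Centred on abundant genes, Il1rl1 and Il4ra stood at -0.17 (unadjusted p = 0.228) and -0.21 (0.171). The list, with a median of -0.37, had an adjusted p of 0.105 by cameraPR and of 0.0318 when its mean statistic was set against random lists. Il17rb, the IL-25 receptor, stood at -0.12 ± 0.16 (adjusted p = 0.798) in the authors' deposited table and turned positive when centred on abundant genes.

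Of 22 TGF-beta responsive genes, 19 lay above the abundance trend (adjusted p = 1.51e-04), with a median log2 of 0.20, and 1, Klf10, passed alone. Smad7, an inhibitor of the pathway, stood at 0.47 ± 0.31 (adjusted p = 0.529) in the authors' deposited table. Of 28 ligands, receptors and SMAD genes, 24 lay above the trend (adjusted p = 0.0309) and none passed alone. Tgfb1 stood at -0.20 ± 0.20, Tgfbr1 at 0.01 ± 0.28 and Tgfbr2 at -0.34 ± 0.17 in the authors' deposited table, with adjusted p of 0.703, 0.993 and 0.345. These 2 lists share 5 genes, the responsive list shares Junb with the immediate-early list, and some members had errors up to 5.89 and 3.38 times those of genes of like baseMean in the SMAD and responsive lists. Neither call held with the trend kept (adjusted p of 0.674 for the responsive list and 0.743, lower, for the SMAD list) or with the fold change in place of the statistic (0.806 for both). The first setting called 0 of 20 simulated raised lists with a baseMean of at least 1000 as higher, and raised lists of lower baseMean were not simulated. The second setting was not simulated. Neither failure thus decides against the calls. The immediate-early list, whose genes respond within minutes to stimulation and to tissue dissociation, had 23 of 29 members above the trend (adjusted p = 1.23e-12). Adjusted over the list alone, Klf4 and Atf3 were higher and Nr4a3 lower, and over all genes none passed. When fold changes were centred on abundant genes, Klf4 (adjusted p = 0.00270) and Atf3 passed over all genes, at 0.75 and 0.87, and Nr4a3 stood at -0.25 (unadjusted p = 0.155). The list's call ended with the trend kept (0.674) and with the fold change in place of the statistic (0.847), with the same limits of these settings. In heat shock and unfolded protein response genes, 17 of 26 lay above the trend (adjusted p = 0.0309), although their median log2 was -0.15 and mean -0.03. With ranks the list did not pass (0.186), nor with the fold change in place of the statistic (0.970). With the trend kept it passed in the other direction, as lower (0.0162), but that setting called 100 of 100 unchanged simulated lists of abundant genes. Of 22 cholesterol synthesis genes, 17 lay below the trend (adjusted p = 0.0349), and with a baseMean of at least 50 the list did not pass (0.0802). Srebf2, their transcriptional regulator and itself 1 of the 22, fell by 0.66 ± 0.17 (adjusted p = 0.0345) in the authors' deposited table. It was the only member to pass alone, and it did not pass when centred on abundant genes.

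**Figure D3:**
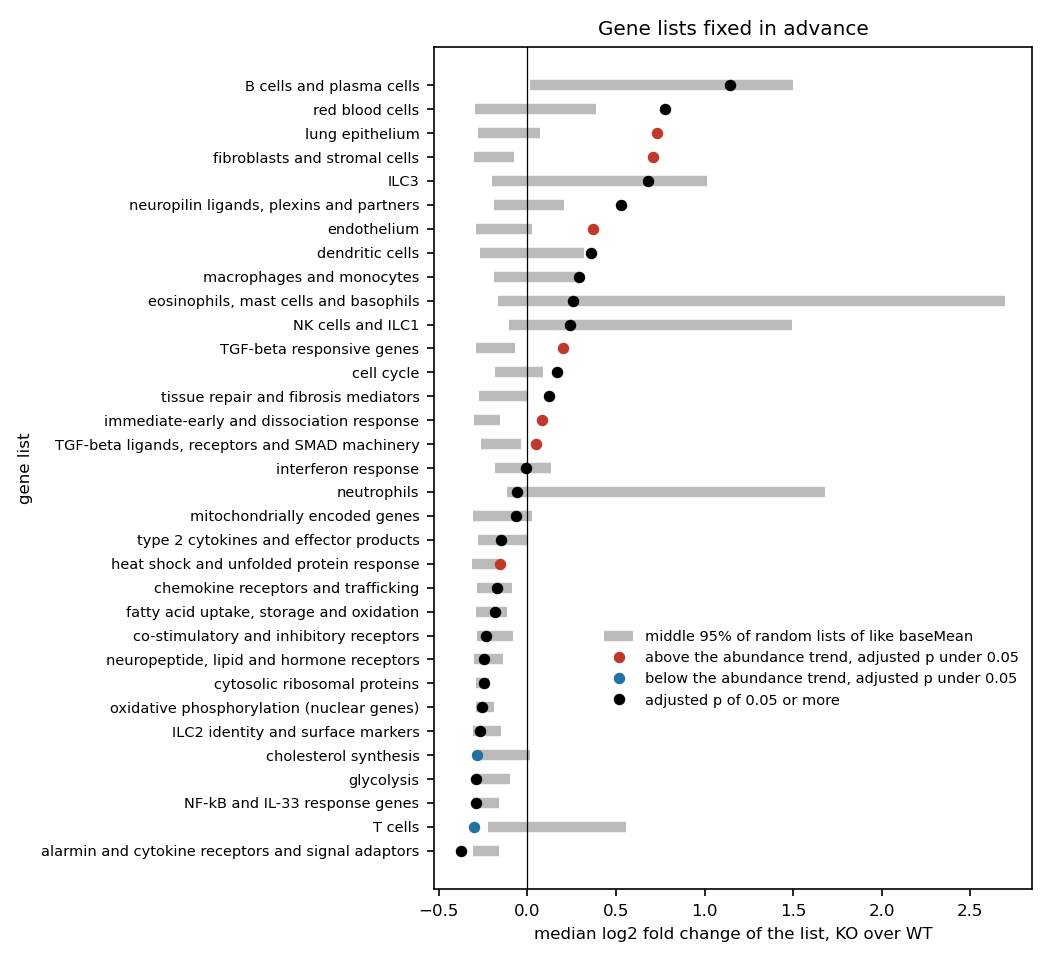
Median log2 fold change (KO over WT, horizontal axis) of the 33 gene lists fixed in advance, with the middle 95% of 10000 random lists of like baseMean as grey bars; red and blue mark lists above and below the abundance trend at an adjusted p under 0.05. The medians of the fibroblast, epithelial and endothelial lists are 0.71, 0.73 and 0.37.

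Markers of other lung cells lay off the trend in 4 of 12 lists. All 16 fibroblast and stromal genes (adjusted p = 0.0309, median 0.71), 16 of 17 lung epithelial genes (0.00650, median 0.73) and 13 of 14 endothelial genes (1.83e-04, median 0.37) lay above the trend. With the trend kept, a setting that called 0 of 20 simulated raised lists of abundant genes as higher, none of these 3 lists passed (0.293, 0.0845 and 0.0845). These calls, like those of all lists, rest on the preset correlation of 0.01, which is too small where members vary together. Whether they hold with an estimated correlation is not known. No member of these 3 lists passed alone, with Col1a1 at 0.99 ± 1.31 and Sftpc at 0.60 ± 1.44 in the authors' deposited table, at baseMean values of 1504 and 6032. T cell markers lay below the trend in 15 of 16 cases (adjusted p = 0.00203), with a median of -0.30 and a mean of 0.08. Cd3g passed alone, and Trbc1 stood at -0.46 ± 0.18 (adjusted p = 0.192) in the authors' deposited table. Not past the test were red blood cells (adjusted p = 0.280), macrophages and monocytes (0.258), dendritic cells (0.213), neutrophils (0.105), ILC3 (0.234), NK cells and ILC1 (0.554), B and plasma cells (0.737) and eosinophils, mast cells and basophils (0.590).

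The remaining lists did not pass cameraPR. They were neuropilin ligands and partners (adjusted p = 0.0526), NF-kB and IL-33 response (0.258), tissue repair and fibrosis (0.205), neuropeptide, lipid and hormone receptors (0.995), chemokine receptors and trafficking (0.995), co-stimulatory and inhibitory receptors (0.105), interferon response (0.289), cell cycle (0.650), glycolysis (0.213), oxidative phosphorylation (0.569), mitochondrially encoded genes (0.348), fatty acid handling (0.917) and ribosomal proteins (0.964). Against random lists of like baseMean, an alternative chosen after seeing the data, the neuropilin list did pass, above them (0.0318), and so did the co-stimulatory list, below them (0.0407). Within them, the prostacyclin receptor Ptgir (-0.64 ± 0.16, adjusted p = 0.0321) and the integrin chain Itgal (-0.63 ± 0.17, 0.0423) fell, and Rpl3l rose, in the authors' deposited table. Adjusted over the list alone, Itgb7 among trafficking genes, Hk1 among glycolytic genes and Mmp9 among neutrophil markers were also lower. Centred on abundant genes, Itgb7 stood at -0.24 (unadjusted p = 0.142) and Hk1 at -0.29 (0.0724). Median, mean and test direction differed in sign for the cytokine, interferon, mitochondrial, chemokine receptor, neuropeptide receptor, fatty acid, NK cell, neutrophil and eosinophil lists.

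The gene test was the authors', two-sided with Benjamini-Hochberg adjustment, and lists were tested with cameraPR in limma with adjustment over 33 lists. The abundance trend was removed first, a step chosen after seeing the data. With the trend kept, 0 lists were higher and 13 lower, and the heat shock and SMAD lists turned direction. That setting called 0 of 20 simulated lists of abundant genes as higher after a raise of 1 standard error. Its failures to call a list higher thus do not decide against such a call. With the fold change in place of the statistic 0 lists passed. That setting does not scale genes by their errors, which are widest at low baseMean. It was not simulated, so whether it can call a raised list is not known. Each replicate was a pool, and the direction rests on the table naming WT first, which Nrp1 being lower in KO does not contradict.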

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

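The settings that kept the trend, took the statistic minus its own trend, used ranks, random lists or the fold change alone, and centring, were chosen after the data were seen. Genes higher, lower and in all in KO numbered 87, 19 and 106 as deposited. They were 21, 2 and 23 without a filter, 22, 13 and 35 with a baseMean of at least 50, 37, 17 and 54 with protein-coding genes alone, 266, 40 and 306 at an adjusted p under 0.1, 1808, 17 and 1825 at 2-fold with an unadjusted p under 0.05, and 225, 2 and 227 when centred. All 35 genes at a baseMean of at least 50 and 89 of the 106 when centred were called in both. The causes were not tested beyond construction: the filters change the number of genes adjusted for, and centring adds 0.25 to each log2 value. Nrp1 kept its direction and its call in the settings run. Of the 161 named genes, 26 passed as deposited. Across settings, named genes kept direction and call in 534 comparisons, lost the call in 37, gained it in 3 and turned in 6, and lists in 196, 16, 18 and 30. Lists higher and lower numbered 7 and 2, against 0 and 13 with the trend kept, 0 and 0 with the fold change alone, 10 and 1 with a baseMean of at least 50, 8 and 4 with random lists, and 9 and 2 with the statistic minus its own trend. Failures to call a list higher with the trend kept, or any list with the fold change alone, do not decide against a call, for the reasons given above. Adjusted p for lists that moved and for named genes that turned direction stand in brackets, and the cause was not tested for any of them. Without a filter, these gained a call: neuropilin partners (0.00293), neutrophils (0.0251). Without a filter, these turned direction: type 2 cytokines (0.886), ILC2 identity (0.886), ribosomal (0.659). With a baseMean of at least 50, these lost their call: cholesterol synthesis (0.0802). With a baseMean of at least 50, these gained a call: neuropilin partners (0.0214), ILC3 (0.0214), macrophages (0.0255). With a baseMean of at least 50, these turned direction: type 2 cytokines (0.753). With protein-coding genes alone, these gained a call: neutrophils (0.0294). With protein-coding genes alone, these turned direction: chemokine receptors (0.984). With centring, these turned direction: mt-Cytb (0.988), Tgfb1 (0.978), mt-Nd2 (0.887), Il5 (0.848), Il17rb (0.861), Lta (0.934). With the trend kept, these lost their call: TGF-beta responsive genes (0.674), immediate-early (0.674), fibroblasts (0.293), lung epithelium (0.0845), endothelium (0.0845). With the trend kept, these gained a call: ILC2 identity (1.43e-05), alarmin receptors (5.43e-09), NF-kB (6.03e-07), co-stimulatory receptors (0.000141), glycolysis (4.80e-05), oxidative phosphorylation (5.69e-09), ribosomal (2.61e-14). With the trend kept, these turned direction: SMAD machinery (0.743), tissue repair (0.674), neuropeptide receptors (0.00140), chemokine receptors (0.0136), heat shock (0.0162), cell cycle (0.732), mitochondrial (0.228), fatty acid (0.00860), NK cells (0.674), eosinophils (0.674). With the fold change in place of the statistic, these lost their call: SMAD machinery (0.806), TGF-beta responsive genes (0.806), immediate-early (0.847), heat shock (0.970), cholesterol synthesis (0.764), T cells (0.642), fibroblasts (0.642), lung epithelium (0.642), endothelium (0.764). With the fold change in place of the statistic, these turned direction: neuropeptide receptors (0.929), chemokine receptors (0.929), cell cycle (0.970), mitochondrial (0.806), fatty acid (0.970), ILC3 (0.970), macrophages (0.970). With random lists, these gained a call: alarmin receptors (0.0318), neuropilin partners (0.0318), co-stimulatory receptors (0.0407). With random lists, these turned direction: type 2 cytokines (0.870), ILC2 identity (0.604), ribosomal (0.823). With the statistic minus its own trend, these gained a call: neuropilin partners (0.0325), red blood cells (0.0275). With the statistic minus its own trend, these turned direction: type 2 cytokines (0.976), ILC2 identity (0.976). With ranks, these lost their call: heat shock (0.186). With ranks, these turned direction: neuropeptide receptors (0.814), chemokine receptors (0.988), ribosomal (0.814). No paired analysis was possible because the columns mapped here carry no sample or replicate. Also not run, since they need values per library assigned to samples, were the pseudocounts of 0.1 and 5, size factors and quantile normalization, the untrended, robust and other-tool fits, the replicate block, leaving out each of the 4 samples, an estimated correlation and fry. Depth limits the low end: the median standard error was 1.68 on the log2 scale for genes with a baseMean under 20 and 0.19 at 1000 or more.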

Other observations

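All tests in this part were chosen after the main results had been seen; for those of exonic length, of unspliced RNA and of the genes around Nrp1 the prediction was written before the value was computed, and for the others after related values were known. The floxed allele and the genotype are the only biological difference the design gives, and it stays open for each pattern as untested.

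Of the rises, 3 lie at 2 repeat-rich loci, which were singled out after their values were seen and not tested as a group. At the start of chromosome 9, 10 of 10 annotated genes were positive, with a median log2 of 3.13, and 3 of these have no adjusted p. Of these, 2 passed the test, led by Gm26870 (chromosome 9, 3000282 to 3038313) at 3.30 ± 0.34 with an adjusted p of 1.45e-17 in the authors' deposited table. At a locus on chromosome 2, Gm10800 (98666547 to 98667301) and Gm10801 stood at 3.53 ± 0.97 and 3.41 ± 0.98 in the authors' deposited table, with adjusted p of 0.0491 and 0.0637. Reads of such near-identical copies cannot be placed with certainty, so the values are uncertain for each gene.

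Low-abundance genes were higher in KO, with a median log2 of 1.79 over the 5600 tested genes with a baseMean under 20, of which 88.1% were positive. RNA of other lung cells in the KO libraries stays open. The abundant markers of epithelium, stroma and endothelium had a median of 0.60, which decides neither way. Its 95% interval (0.42 to 0.74) came from resampling genes and leaves out the spread between pools. The 1381 sensory receptor genes, chosen as genes that lung cells do not use, had a median of 3.32, and 91.8% were positive. Their summed means, derived from the fitted values, were 1066 in WT and 5816 in KO. Singly these genes lie near the floor, 82 of them with an adjusted p, and they themselves belong to the pattern. Unspliced RNA of expressed genes in the KO libraries also stays open. Models inside abundant genes gained less per kb than models outside every other gene. The difference of medians was -0.771 (-1.31 to -0.247) normalized counts per kb. Unspliced RNA would give a positive difference, so the value ran against the prediction written before it was computed. The outside models had a median baseMean of 2.63, under the limit for sets that was chosen after results had been seen. By that later rule alone the difference was taken to decide nothing. Genomic DNA or other sequence read without regard to genes may contribute and stays open: across the sensory receptor genes the KO minus WT difference followed exonic length with a rho of 0.111 (0.0572 to 0.159), or 0.0994 over the 1091 protein-coding ones, short of the 0.2 set in advance and not clearly under 0.1. Permuting lengths over all the sensory receptor genes gave a p of 0.0005 for the rho of 0.111, which takes genes as independent.

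Some markers of lung tissue had wide deposited errors. Standard errors were set against those of genes of like baseMean. Over 34 epithelial, stromal and red blood cell markers with a baseMean of at least 100, the median ratio was 4.52 (3.49 to 5.52). The medians were 1.17 for endothelial, 1.25 for macrophage, 1.21 for dendritic cell and 1.02 for ILC2 identity genes. Single members of these lists reached 3.71, 4.06, 1.38 and 2.81. Low read numbers for the 34 markers are argued against by their ratio. RNA of other lung cells in amounts that differ between libraries of one genotype could account for it but stays open. The ratio is what drew notice to these markers, and values per library were not used. At the median, endothelial genes did not share it, although some members did. Gsn, Sftpc and Hba-a1 were the most abundant markers of these lists, at baseMean values of 2898, 6032 and 2899 in the authors' deposited table.

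Called genes with a baseMean of at least 100 lay near each other more often than random sets, with 4 pairs within 1 Mb among 27 genes, against a median of 0 and a 95th percentile of 2. The pairs were Bpnt1 with Eprs, Cd3g with Il10ra, Abca7 with Gadd45b, and Fau-ps2 with Gm12735, the last 2 being models named after their values were seen. The falls among these genes did not pass when centred on abundant genes. Fau-ps2 and Gm12735 both lie within Drg1 on the same strand, so their reads cannot be assigned with certainty here. Chromosomal segments that differ between the 2 genotypes, a passenger or substrain segment, may be one source of the 4 pairs, and Nnt, which is deleted in part in some C57BL/6 substrains, was among the falls. Co-regulated or run-through neighbours were not separated from this. A segment carried along with the floxed Nrp1 allele cannot be told apart from chance, as 12% of 25 genes within 5 Mb of Nrp1 had an unadjusted p under 0.05, inside the range of random sets (0 to 20%).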
